A study of Mus musculus with 6 samples.

How the data were processed

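Gene expression was measured with 6 Illumina mouse expression beadchips carrying 25697 probes, each hybridised with biotin-labelled RNA from 1 sample of STHdh cells, an immortalized mouse cell line of striatal origin. Per the labels, total RNA was column-purified and treated with DNase I. Groups were taken from the sample titles, which give 3 control and 3 Foxp1-transfected samples. The control titles carry the name of the expression plasmid pcDNA, while their genotype field calls the cells wild-type, so the labels leave open whether the control cells received an empty plasmid. The labels do not say whether the replicates came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

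The deposited table of unnormalized values holds a probe intensity on a linear scale and a detection p-value for each probe and array, per the file headers. The submitters' processing notes name GenomeStudio, with no version. Between 29.5% and 31.6% of the intensities on each array were below 0, so an array background had been subtracted by the authors before the intensities were deposited. The detection p-values of the deposited table move in steps of 1 in 798. A second deposited table holds the authors' processed values, whose scale and normalization are not given in the sources used here. Its values were read as log2 because they follow the log2 intensities of the deposited table array by array (r of the deviations from the probe mean between 0.921 and 0.987 for an array's own column, at most 0.538 for another column). The upper quantiles of its 6 columns were equal (75th percentile 9.06, maximum 14.81) and the column medians lay at 6.32, which is what quantile normalization gives. Its Foxp1 difference, 2.55 against 2.62 here, fits base 2, while any offset and the exact method stay unknown. That table served as an alternative only.

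Intensities were background-corrected with the normal-exponential model of limma's neqc function, which inferred the background from the detection p-values, with an offset of 16, and were then quantile-normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 12136 probes or 47.2%. The 2 groups were compared probe by probe with limma (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05 on the adjusted p. All log2 differences are Foxp1-transfected minus control, and each rests on 3 arrays per group. Errors are standard errors (SE) of the difference unless given as SD. A gene was represented by its kept probe with the highest mean over all 6 arrays, which left 8789 genes, of which 2372 had 2 or more kept probes. The offset pulls differences of dim probes towards 0. Where no array of a group detected a probe, the fold is given as a lower bound: the mean of the bright group against, on each array of the other group, the higher of the lowest level among detected probes and the probe's own level.

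The array's gene symbols were updated through the synonyms of the RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probes, 17548 carried a current symbol, 7082 matched 1 gene as a synonym, 116 matched several genes and 924 matched none, and the last 2 classes kept the array's name. A further 27 probes had symbols turned into dates or numbers by a spreadsheet, 12 of them kept, and were left unnamed, and 0 of these passed the threshold. The files name no genome build, so no coordinates are given.

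The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes are the Foxp family, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out provisional symbols, and up to 4 members of each gene list with the smallest p past the threshold, or the 2 with the smallest unadjusted p where none passed. Other genes named in the text were chosen after their values were seen. Values of 2 single genes that enter the counts are not reported here. The 23 lists cover immune signalling, brain cell types, stress, growth and metabolism. The 20 lists with at least 5 kept genes were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. The remaining 3 (the Foxp family, oligodendrocyte markers, and microglia and macrophage markers) are described without a list test. Camera was repeated with a correlation estimated from the residuals, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, was run beside it.

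The titles number the replicates 1 to 3 in both groups. Deviations from the group means correlated between same-numbered arrays at 0.257, 0.115 and 0.401, each over 0.1, so the numbers were taken to pair the arrays, on the evidence of the data rather than the labels. Foxp1 replicate 2 correlated higher with control replicate 1 (0.151) than with its own number, and control replicate 2 higher with Foxp1 replicate 1 (0.121). Deviations within a group sum to 0, so a trait shared by the replicate 3 arrays alone raises the correlations among replicates 1 and 2. The evidence that numbers 1 and 2 mark pairs is therefore weak. The planned comparison has no block, and a fit with the replicate number as a block is reported beside it where it changes a call.

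The comparison step was tested on data simulated from the levels and spread of the 12136 kept probes, with 3 arrays per group. It recovered 53.7% of 54 probes changed 1.5-fold, 96% of 75 changed 2-fold and 100% of 71 changed 3-fold. There 4.44% of its calls were false, and with no simulated change it made 0 calls. The simulated noise was independent between probes and arrays, so these rates leave out noise that probes or arrays share. The background correction and the detection filter were not simulated. The number of arrays, not a read depth, limits the precision. Alternatives covered the background correction, the normalization, the authors' processed values, the detection filter, the replicate block, the variance prior, array weights, the choice of probe, a 1.5-fold minimum, the list test and each array left out in turn. Leaving out both replicate 3 arrays, and the block together with an estimated correlation, were added after the data were seen. A slide block was not run because the files name no slide. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.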

Results

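Expression was profiled in 6 samples of STHdh cells, of which 3 were controls and 3 had been transfected with Foxp1, a forkhead transcription factor expressed in the striatum. The series asks, by its title, whether Foxp1 represses immune signalling genes in the central nervous system. The arrays detected between 11789 and 12342 probes each, 45.9% to 48.0% of the 25697 probes. Median probe intensity was 29.2, 31.8 and 77.0 on control arrays 1 to 3 and 36.6, 38.3 and 64.5 on Foxp1 arrays 1 to 3, so the replicate 3 array of each group was brighter than the rest before normalization. After normalization, the correlation across probes between any pair of arrays lay between 0.982 and 0.995. The component with the most variance (41.7%) separated the Foxp1 arrays from the controls, and the next (29.3%) set the replicate 3 arrays apart.

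Foxp1 was higher on each transfected array than on any control array. Its probe (ILMN_1252078) had intensities of 688, 621 and 1048 on the control arrays and of 4967, 4979 and 5250 on the Foxp1 arrays. The normalized log2 level was 9.69 ± 0.22 (SD, n = 3) in controls and 12.31 ± 0.29 (SD, n = 3) in transfected cells. The log2 difference was 2.62 ± 0.17 (SE), or 6.13-fold (limma adjusted p = 0.0005), and it passed in all 6 fits that left out 1 array. Where this probe lies relative to the transfected sequence is not known here. Of its family, Foxp4 differed by -0.05 ± 0.12 (adjusted p = 0.879), while the 4 probes for Foxp2 and the 3 for Foxp3 were detected on 0 arrays.

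By log2 difference, with the background correction used, the largest rises beside Foxp1 included Atf3, a stress-induced transcription factor (2.47 ± 0.14, 5.53-fold), Slc6a19, a transporter of neutral amino acids (2.09 ± 0.15, 4.27-fold), and Ccl5, a chemokine that attracts T cells (1.88 ± 0.23, 3.69-fold). Slc6a19 was detected on 2 control arrays, and its control levels lay near the lowest detected ones, so its fold is uncertain. Other large rises came from genes that no control array detected, for which only a lower bound holds and whose order depends on the background correction (without it Grhl2 differed by 3.97, Svop by 3.20 and Oasl1 by 3.00, against 2.62 for Foxp1). They were Vgf, a precursor of secreted neuropeptides (2.58 ± 0.17, at least 5.56-fold), Svop, a synaptic vesicle protein listed on the array as 1110030H18Rik (2.54 ± 0.15, at least 3.39-fold), and Oasl1, an antiviral protein of the oligoadenylate synthetase-like family (2.38 ± 0.11, at least 3.04-fold). Rgcc, a regulator of the cell cycle listed as 1190002H23Rik, rose by at least 2.98-fold, Nppb, the precursor of B-type natriuretic peptide, by at least 2.36-fold, and Grhl2, an epithelial transcription factor listed as Tcfcp2l3, by at least 1.77-fold. The adjusted p of these 9 genes lay between 0.000293 and 0.00742, and among them Ccl5 lost its call without Foxp1 replicate 2 (0.0642).

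The largest falls were those of Eif3h, a subunit of a translation initiation factor (-1.91 ± 0.11, 3.75-fold lower), Mgp, an inhibitor of matrix calcification (-1.76 ± 0.22, 3.40-fold lower), Tmem119, a membrane protein used as a microglial marker (-1.41 ± 0.13, 2.66-fold lower), and Mdh2, the mitochondrial malate dehydrogenase (-1.31 ± 0.09, 2.48-fold lower). Rab7b, a small GTPase of endosomal traffic, fell by 1.31, Cbr2, a carbonyl reductase, by 1.13, Prelp, a small leucine-rich proteoglycan of the matrix, by 1.08, and Ncald, a neuronal calcium sensor, by 1.08. Tle2, a Groucho-type corepressor, and Ncoa1, a nuclear receptor coactivator, were detected on no Foxp1 array and were at least 1.70-fold and at least 1.71-fold lower. The adjusted p of these 10 genes lay between 0.000298 and 0.0242. Without Foxp1 replicate 1 or 2, the calls of Cbr2 (highest adjusted p 0.0752), Mgp (0.0692), Prelp (0.0723), Ncald (0.0937), Ncoa1 (0.0934) and Tle2 (0.0692) were lost, and that of Ncald also without control replicate 1 (0.0564) or 2 (0.0534). Ncoa1 also lost its call with no background correction (adjusted p = 0.0575) and with no detection filter (0.0655), and Ncald with no detection filter (0.0545). Of the 20 genes, Oasl1 alone had a further kept probe, which also rose.

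**Figure D1:**
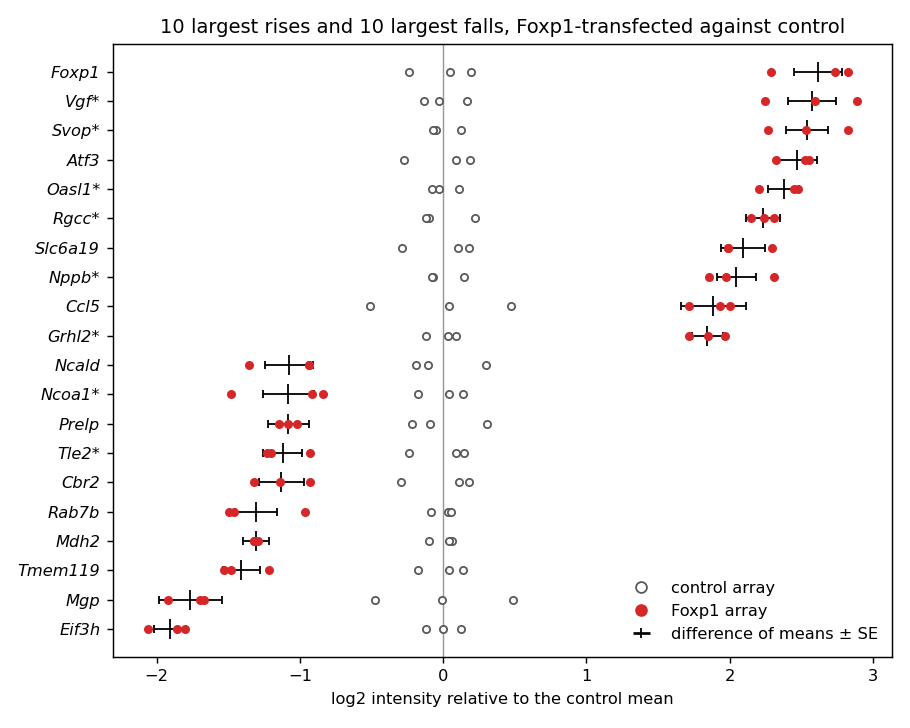
Normalized log2 intensity of each array relative to the control mean (horizontal axis) for the 10 largest rises and the 10 largest falls, with open circles for control arrays, filled circles for Foxp1 arrays and a bar for the difference of means ± SE (n = 3 per group). An asterisk marks a gene that 1 group's arrays did not detect, and for each gene shown the Foxp1 arrays lie on 1 side of the control arrays.

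In all, 240 of 8789 genes (2.73%) passed an adjusted p of 0.05 with limma, 139 higher and 101 lower in transfected cells. By the fitted difference, 55 of them differed at least 2-fold (43 higher, 12 lower). These include genes for which only a smaller lower bound holds, such as Grhl2 (at least 1.77-fold) and Tle2 (at least 1.70-fold). Each of the 240 had its 3 Foxp1 arrays on 1 side of the 3 control arrays, as had 2267 of all genes (25.8%, where chance gives 10%). The median rise was 0.77 and the median fall -0.65, against a median SE of 0.12 over all genes. The count changed with the array left out. It was 93 without control replicate 1, 75 without control replicate 2 and 265 without control replicate 3. It was 29 without Foxp1 replicate 1, 28 without Foxp1 replicate 2 and 90 without Foxp1 replicate 3. Each such fit also rests on fewer samples, which by itself can end calls. Of the 53 named genes past the threshold, 15 also passed in each of the 6 fits that left out 1 array: Foxp1, Atf3, Slc6a19, Cdkn1a, Cdkn1c, Chac1, Trib3, Fos, Isg15, Pmaip1, Tnfaip3, Eif3h, Mdh2, Rab7b and Tmem119. Grhl2, H2-Bl, Nppb, Oasl1, Rgcc, Svop, Traf1 and Vgf passed in each of the 3 fits that gave them a value. Without a Foxp1 array their probes did not meet the detection filter. Besides Foxp1, 52 named genes passed on all 6 arrays. Among those whose probe stayed above the detection filter, the call was lost for 15 of 50 without control replicate 1, 14 of 50 without control replicate 2, 1 of 50 without control replicate 3, 27 of 43 without Foxp1 replicate 1, 28 of 43 without Foxp1 replicate 2 and 11 of 43 without Foxp1 replicate 3. The sign was kept in each of these fits, which says little, because the groups of these genes do not overlap.

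Immune genes moved in both directions, and most did not pass the test. Of 129 distinct kept genes on the 6 immune lists, 10 rose, 2 fell and 117 did not pass (9 rose and 4 fell with the replicate block), and 54 had a positive and 75 a negative difference (median -0.06). Over all tested genes 2.73% passed, and 4350 had a positive and 4439 a negative difference. The immune lists named more genes than were kept, from 31 against 8 for complement and acute phase to 42 against 30 for cytokine receptors. The genes not kept give no value here. Among the 23 kept interferon-stimulated genes, 4 rose: Oasl1, Ccl5, Isg15, a ubiquitin-like antiviral protein (1.08 ± 0.11, adjusted p = 0.00334), and Irf9, the DNA-binding part of the interferon-activated complex (0.53 ± 0.11, adjusted p = 0.0449, a call lost with the replicate block, 0.0503). Lgals3bp, a secreted galectin-binding protein, fell (-0.74 ± 0.12, adjusted p = 0.0242), and 18 did not pass. As adjusted over the list alone, 7 rose and 1 fell. The list's median was 0.08 and camera placed it higher than other genes (adjusted p = 0.0299), with adjusted p = 0.179 with an estimated correlation and adjusted p = 0.0702 with the replicate block. That call was also lost without control replicate 1 (adjusted p = 0.0573, median 0.00), without Foxp1 replicate 1 (0.101), 2 (0.235) or 3 (0.145, median 0.04), with no detection filter (0.0847, median 0.02), with the stricter one (0.313, median -0.06) and without both replicate 3 arrays (0.216, median 0.01), a setting chosen after the data were seen. Over the alternatives run with camera its adjusted p ran from 0.0151 to 0.416. With fry, which asks about the list alone and not about other genes, the adjusted p was 0.0063.

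Among 20 kept cytokines and chemokines, Ccl5, Il11, an interleukin of the gp130 family (1.11 ± 0.14, adjusted p = 0.0094), and Tnfsf13b, a B-cell survival factor (0.81 ± 0.11, adjusted p = 0.0127), rose, 0 fell and 17 did not pass, while 4 rose and 4 fell when adjusted over the list alone. With the replicate block 1 fell, Il18 (-0.82 ± 0.17, adjusted p = 0.0505, and 0.0295 with the block). The list median was -0.16 and the mean 0.03, camera pointed down (adjusted p = 0.566), and the median was 0.02 without the detection filter. Of 37 genes of innate sensing and NF-kB signalling, 2 rose, Tnfaip3, an inhibitor of NF-kB (1.21 ± 0.11, adjusted p = 0.00203), and Traf1, a signalling adaptor that no control array detected (at least 1.83-fold, adjusted p = 0.00553). There 3 rose and 0 fell when adjusted over the list alone, and the list did not pass (median 0.01, adjusted p = 0.762). Among 30 cytokine receptors and JAK-STAT genes, Fas, a death receptor, rose (0.84 ± 0.15, adjusted p = 0.032) and 29 did not pass, of which Il17rc (-0.49 ± 0.11, adjusted p = 0.0665) fell with the replicate block (0.0486). With p adjusted over the list alone 1 rose and 1 fell (list median -0.07, camera adjusted p = 0.14).

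Among 15 genes of the MHC and antigen processing, H2-Bl rose by at least 1.84-fold (adjusted p = 0.00245) from a level that no control array detected. Class I genes have near-identical copies, so the identity of what this probe read is uncertain. The other 14 did not pass, and adjusted over the list alone 1 rose and 1 fell. The list's median was -0.02 and its mean 0.06, with camera pointing down (adjusted p = 0.817). Of 8 complement and acute phase genes, Cp, the ferroxidase ceruloplasmin, fell (-0.71 ± 0.11, adjusted p = 0.0176), and adjusted over the list alone 0 rose and 1 fell. The list had a median of -0.24 and did not pass with camera (adjusted p = 0.0715, 0.246 with an estimated correlation and 0.416 with that and the replicate block). Of 17 alternatives run with camera, 10 did not pass, up to 0.781 with no detection filter (median -0.03), and 7 passed: the replicate block alone (0.0305), median scaling (0.0321), both replicate 3 arrays left out (0.034), and the fits without control replicate 1 (0.0374) or 2 (0.00907) or Foxp1 replicate 2 (0.00775) or 3 (0.0251). Taken alone with fry, the list passed (0.00791). Among the immune genes, Lgals3bp and Fas lost their calls in all fits without 1 array but that without control replicate 3 (highest adjusted p 0.127 and 0.126), Cp without control replicate 1 or any of the Foxp1 arrays (0.0986), Tnfsf13b without control replicate 2 or Foxp1 replicate 1 or 2 (0.0857) and Il11 without Foxp1 replicate 1 or 2 (0.0719).

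Immediate early, p53 target and stress response genes made up the 3 lists with the most risers. Of 21 immediate early genes, which follow stimulation of a cell within minutes, 8 rose and 0 fell, led by Atf3, Fos (1.40 ± 0.13, adjusted p = 0.00219), Arc, a neuronal activity gene (0.72 ± 0.10, adjusted p = 0.0102), and Fosb (1.22 ± 0.17, adjusted p = 0.0108). As many as 12 rose and 0 fell when adjusted over the list alone, and the list median was 0.37 (camera adjusted p = 9.6e-09, and adjusted p = 0.13 with an estimated correlation). Of 30 p53 targets and apoptosis genes, 8 rose and 0 fell, among them Cdkn1a, a cyclin-dependent kinase inhibitor (1.33 ± 0.10, adjusted p = 0.00116), Pmaip1, a pro-apoptotic BH3-only protein (1.20 ± 0.11, adjusted p = 0.00193), Trp53inp1 (1.20 ± 0.15, adjusted p = 0.0084) and the DNA damage-inducible Gadd45a (0.80 ± 0.10, adjusted p = 0.00679). Here 13 rose and 0 fell when adjusted over the list alone, and the list median was 0.16 (camera adjusted p = 2.24e-06, and adjusted p = 0.13 with an estimated correlation).

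Of 27 unfolded protein and stress response genes, 5 rose and 0 fell. Besides Atf3 these included Chac1, which degrades glutathione (0.93 ± 0.08, adjusted p = 0.00203), Trib3, a pseudokinase (0.98 ± 0.09, adjusted p = 0.00219), and Ddit3, a pro-apoptotic transcription factor (1.01 ± 0.12, adjusted p = 0.00594). Adjusted over the list alone, 5 rose and 1 fell, and the list median was 0.13 (camera adjusted p = 0.00842, and adjusted p = 0.13 with an estimated correlation). Without control replicate 1 the median was 0.07 and without Foxp1 replicate 3 it was 0.06, with the call kept in both fits. Atf3 belongs to both this list and the immediate early list. Arc, Fosb, Ddit3, Gadd45a and Trp53inp1 lost their calls without Foxp1 replicate 1 or 2 in at least 1 of the fits (highest adjusted p 0.0792, 0.0752, 0.0583, 0.0684 and 0.0609), and Arc also without control replicate 2 (0.0517).

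Cholesterol synthesis genes were lower as a group. All 18 kept members had negative differences, with a median of -0.31, and camera placed the list below other genes (adjusted p = 6.62e-07, and adjusted p = 0.0854 with an estimated correlation). Nsdhl (-0.60 ± 0.11, adjusted p = 0.032) and Cyp51 (-0.51 ± 0.10, adjusted p = 0.0454), both of which remove methyl groups on the way from lanosterol, fell and 16 did not pass. The calls of Nsdhl and Cyp51 were lost with median scaling (adjusted p = 0.0532 and 0.0767) and with no detection filter (0.0525 and 0.0642). In this list 0 rose and 9 fell when adjusted over the list alone. Of 41 extracellular matrix and adhesion genes, 0 rose and 5 fell, among them the proteoglycan Bgn (-0.65 ± 0.09, adjusted p = 0.0105), the elastin cross-linking enzyme Loxl1 (-0.60 ± 0.09, adjusted p = 0.0174), the collagen chain Col6a1 (-0.68 ± 0.12, adjusted p = 0.0277) and the gelatinase Mmp2 (-0.51 ± 0.09, adjusted p = 0.0335). The count was 0 higher and 7 lower when adjusted over the list alone. The list median was -0.12 (camera adjusted p = 0.000565, and adjusted p = 0.298 with an estimated correlation), and the list call was lost without both replicate 3 arrays (0.0769), also chosen after the data were seen, with a range of 7.45e-05 to 0.611 over all alternatives. Calls of single members were lost as well: Cyp51 lost its call in each of the 6 fits without 1 array (highest adjusted p 0.181), Nsdhl, Loxl1 and Mmp2 in all but that without control replicate 3 (0.16, 0.113 and 0.164), Col6a1 without control replicate 1 or any of the Foxp1 arrays (0.146) and Bgn without Foxp1 replicate 1 or 2 (0.0815).

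Growth factor and morphogen genes were mixed. Of 46 kept members, 2 rose, among them Vegfa, the vascular growth factor (0.63 ± 0.11, adjusted p = 0.0336), Bmp4, a morphogen, fell (-0.71 ± 0.13, adjusted p = 0.0347), and 43 did not pass. With the replicate block Fst rose as well (0.62, 0.0364) and Tgfbi fell (-0.61, 0.0273), which makes 3 higher and 2 lower. Adjusted over the list alone, 5 rose and 8 fell. The list median was -0.16 (camera adjusted p = 0.04, and adjusted p = 0.246 with an estimated correlation), and its call was lost without control replicate 3 (0.172), without Foxp1 replicate 3 (0.141), with no detection filter (0.147), with array weights (0.217), with the mean over a gene's probes (0.072), with fry (0.0862) and without both replicate 3 arrays (0.141), in a range of 0.0134 to 0.441. Bmp4 lost its call without control replicate 1 or 2 or Foxp1 replicate 1 or 2 (highest adjusted p 0.167), and Vegfa in all but the fit without control replicate 3 (0.16). Vegfa was the 1 riser among 23 glycolysis and hypoxia genes, of which 22 did not pass (median -0.08, list adjusted p = 0.566), and adjusted over the list alone 3 rose and 1 fell. With the replicate block 2 rose, the other being Ndrg1 (0.52, adjusted p = 0.0386).

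The 45 cell cycle genes (median 0.00) were not set apart from other genes by camera (adjusted p = 0.41), while fry, which tests them alone, passed (adjusted p = 0.0063), and the 2 members that rose, also when adjusted over the list alone, are both cyclin-dependent kinase inhibitors, Cdkn1a and Cdkn1c (1.40 ± 0.11, 2.64-fold, adjusted p = 0.00116). Of 14 striatal and neuronal genes, Foxp1 itself and Nefm, a neurofilament subunit (0.86 ± 0.14, adjusted p = 0.0238), rose, Stmn2, a regulator of microtubules in growing neurites, fell (-0.65 ± 0.12, adjusted p = 0.032), and 11 did not pass. With the replicate block 2 fell, the other being Ncam1 (-0.53, adjusted p = 0.0386). Adjusted over the list alone, 2 rose and 3 fell. The list median was -0.13 and its mean 0.08, with camera pointing down (adjusted p = 0.455), and the median was 0.00 without the detection filter. Nefm and Stmn2 lost their calls without control replicate 1 or 2 or Foxp1 replicate 1 or 2 (highest adjusted p 0.0994 and 0.159), and Nefm also without Foxp1 replicate 3 (0.0624).

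Markers of other brain cell types were measured as well. The samples are of a cell line, so a changed marker is read here as the level of that gene. It is not read as a change in the share of another cell type. Of 3 detected microglia and macrophage markers, Tmem119 fell and the other 2, among them Cd68 (-0.26), did not pass. Of 3 oligodendrocyte markers, Pdgfra, a receptor of their precursors, fell (-0.61 ± 0.12, adjusted p = 0.0471), a call lost with the replicate block (0.0524) and in each fit without 1 array except that without control replicate 3 (highest adjusted p 0.172). In both of these lists, adjusted over the list alone, 0 rose and 1 fell. Of 5 endothelial and mural markers, Esam, an adhesion molecule that no control array detected, rose by at least 1.60-fold (adjusted p = 0.0186, and 0.0674 without control replicate 1), as the 1 riser also when adjusted over the list alone. The list had a median of -0.14, a mean of 0.07 and camera pointing down (adjusted p = 0.566).

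No gene of 4 lists passed with limma. Of 6 astrocyte markers (median -0.11, adjusted p = 0.566), 3 had an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 1 fell. The smallest p belonged to Sox9 (0.50 ± 0.15, adjusted p = 0.125) and Slc1a3, a glutamate transporter (-0.61 ± 0.18, adjusted p = 0.137, and 0.0455 with the replicate block). Of 21 axon guidance genes (median 0.06, adjusted p = 0.455), 6 had an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 1 fell. These were the receptor Epha2 (0.61 ± 0.14, adjusted p = 0.0745, and 0.0252 with the replicate block) and the guidance cue Sema3f (-0.60 ± 0.13, adjusted p = 0.058, and 0.0274 with the replicate block). Of 36 oxidative phosphorylation genes (median 0.07, adjusted p = 0.324), 1 had an unadjusted p under 0.05, the complex I subunit Ndufs4 (0.35 ± 0.13, adjusted p = 0.227), followed by Uqcrc1 (-0.22 ± 0.12, adjusted p = 0.395). Of 42 ribosomal protein genes (median 0.06, adjusted p = 0.31), 0 had an unadjusted p under 0.05, with Rps19 (0.23 ± 0.11, adjusted p = 0.305) and Rpl22 (-0.17 ± 0.09, adjusted p = 0.353) closest. Adjusted over the list alone, 0 genes of either of these lists passed. The oxidative phosphorylation list passed without control replicate 3 (0.0216) and the ribosomal list without control replicate 2 (0.0464), with ranges of 0.0216 to 0.775 and 0.0464 to 0.716 over their alternatives.

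**Figure D2:**
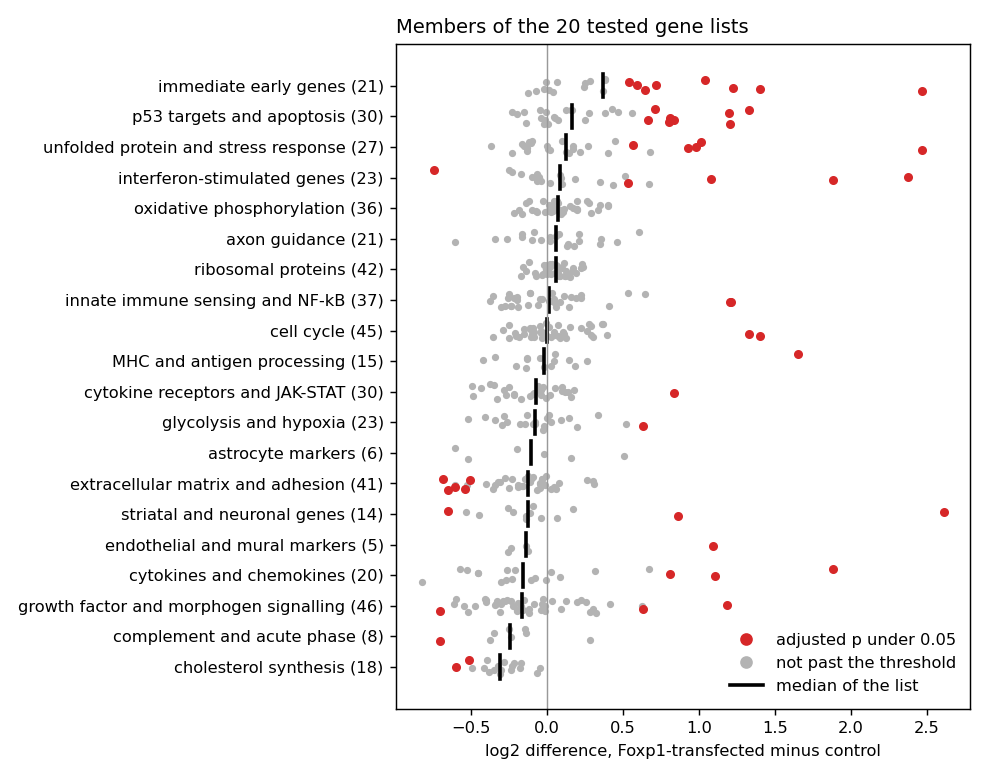
Log2 difference between Foxp1-transfected and control cells (horizontal axis) of each kept member of the 20 tested lists, with the number of members in parentheses, the median as a black bar and genes past an adjusted p of 0.05 in red. Lists are ordered by their median, from 0.37 for immediate early genes to -0.31 for cholesterol synthesis, and the 7 lists that passed were called at a preset correlation, 0 of them with an estimated one.

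Of the 20 lists, camera called 7 at the preset correlation, 4 upward and 3 downward. With an estimated correlation 0 passed (lowest adjusted p 0.0854), and fry called 8. The estimate lay below the preset 0.01 for cholesterol synthesis (-0.0048), stress response (-0.0023) and interferon-stimulated genes (-0.0049). A higher correlation therefore cannot be what ended those calls. For the other called lists the estimate was higher, from 0.0121 to 0.139, but their lost calls need not come from correlation either. With simulated noise independent between probes, a shifted list had a camera adjusted p of 9.07e-34 at the preset correlation. With an estimated one it had 0.00251. The estimated setting is thus the weaker test even where genes do not share noise, and a call lost there is no evidence against a list.

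Probes of the same gene did not always move together. Of the genes with several kept probes, 77 further probes passed the threshold. For 43 genes a further probe passed while the representing probe did not, so the count of changed genes leaves them out. Among the named genes past the threshold, Trib3, Nsdhl and Col6a1 had further kept probes that did not pass. Of their 3, 4 and 2 kept probes, all of the same sign within a gene, 1 each passed. Of the 77 probes, 7 lay over 1 log2 unit from the probe that represented their gene, and 4 of these 7 had the other sign. The widest gap was in Actb, which encodes cytoplasmic actin. Probes ILMN_2846865 and ILMN_2588055 rose by 5.10 ± 0.54 and 5.09 ± 0.52 (adjusted p = 0.00391 and 0.00347), while the other 3 Actb probes differed by -0.06, -0.25 and 0.13 and did not pass. Of these 3, ILMN_2698799 and ILMN_1377923 came within 1.16-fold and 1.09-fold of the brightest probe of an array, so they had little room to rise.

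**Figure D3:**
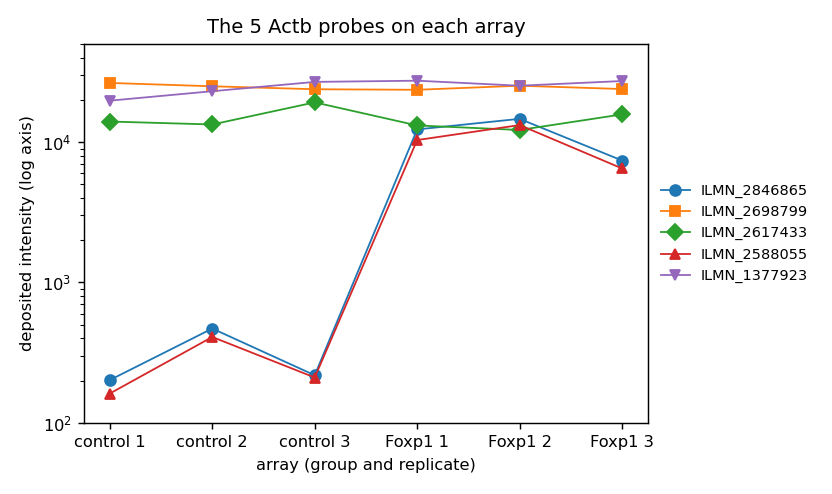
Deposited intensity (vertical log axis) of the 5 Actb probes on each of the 6 arrays (horizontal axis), 1 line per probe. Probes ILMN_2846865 and ILMN_2588055 lie between 162 and 469 on the control arrays and between 6489 and 14643 on the Foxp1 arrays, while the other 3 stay at or above 12197 on each array.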

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

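The 7 results here come from probes that the gene-level comparison did not use, because a brighter probe represented their gene, and each passed the threshold at over 1 log2 unit from that probe. The tests of the Actb probes were chosen after the result was seen.

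The most marked pattern was in Actb. Probe ILMN_2846865 rose by 5.10 (34.2-fold) and probe ILMN_2588055 by 5.09 (34.1-fold), on all 3 Foxp1 arrays, while the 3 brightest Actb probes did not pass. A rise of the whole Actb transcript is argued against by probe ILMN_2617433, which lay at least 1.54-fold below the brightest probe of each array, so that it had some room to rise, and differed by -0.25 (95% interval -0.46 to -0.03). A fault of 1 array is argued against by the smallest gap between any Foxp1 and any control array over both probes, 3.14 log2 units. A sequence brought in with the transfected DNA may be read by these probes, and this stays open: on the normalized scale both ordered the 3 Foxp1 arrays as the Foxp1 probe did, with a range of 1.47 log2 units for ILMN_2846865, but by deposited intensity Foxp1 replicate 3 was the highest for the Foxp1 probe (5250) and the lowest for ILMN_2846865 (7392) and ILMN_2588055 (6489). With 3 arrays this cannot be decided, and the probe sequences were not used here. An effect of Foxp1 on an Actb variant was not tested and stays open too.

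The other 5 probes are given as values. For Chka, which encodes a choline kinase, probes ILMN_2702540 and ILMN_3099242 rose by 0.92 and 0.75, while the representing probe differed by -0.33. For Oasl1, probe ILMN_2717366 rose by 1.34, in the same direction as the representing probe (2.38). For Armc9, probe ILMN_2595651 rose by 0.94, while the representing probe differed by -0.08. For Siah1b, probe ILMN_1217391 fell by 0.87, while the representing probe differed by 0.14.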

How the results depend on the processing

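Leaving out both replicate 3 arrays, and the block with an estimated correlation, were chosen after the data were seen. The rise of Foxp1 kept its direction and call in each alternative run (2.51 to 2.78, adjusted p 3.56e-06 to 0.0122). The count of changed genes (240; 139 higher, 101 lower) moved by ratio most with the arrays: leaving out 1 gave 28 to 265 changed, 21 to 170 higher and 6 to 95 lower genes, fewer samples being part of each such fit. Without control replicates 1 to 3 it was 93, 75 and 265, and without Foxp1 replicates 1 to 3 it was 29, 28 and 90. Without both replicate 3 arrays 92 genes were higher (163 changed, 71 lower), and 113 of the 163 were among the 240. Array weights gave 753 changed (366 higher, 387 lower), including the 240, and an intensity trend with a robust prior 391 (185 lower). Fewer genes were lower with median scaling (63) and with no detection filter (52), and of 52 named calls 5 and 13 were lost there, 2 with no background correction, and 7 of 41 without both replicate 3 arrays. The causes were not tested. Of the 7 called lists, 0 passed with an estimated correlation, with or without the replicate block. The replicate block gave 333 changed genes, 227 of them among the 240, and changed no call of a named gene or list besides those given with their blocked values; over all members of the lists it ended 2 calls and added 11. None of the 240 genes turned sign in any fit that gave it a value. For fits that left out arrays this was nearly set in advance, because the groups of these genes do not overlap. Signs turned for Foxp4 and for the medians of some lists that did not pass, and of the interferon-stimulated genes under the stricter filter. The higher share, 57.9%, was 67.9% without a filter, 47.8% with the stricter one and 54.4% to 79.3% without 1 array (79.3% without Foxp1 replicate 1). A 1.5-fold minimum left 171 genes. A slide block was not run. Signal over background limits the 32 changed genes that 1 group's arrays did not detect, for which folds are bounds.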

Other observations

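The tests of families, stress and interferon patterns in this part were chosen after the results were seen. The count over other splits of the arrays was planned.

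Families of genes were looked at by name after the changed genes were seen, with no test of enrichment. Both detected grainyhead-like factors, which regulate epithelial genes, rose: Grhl2, and Grhl1 by 1.09 ± 0.21 (adjusted p = 0.0421). Grhl1 was detected on 2 control arrays, so its difference starts near the detection limit. Of 10 AP-1 genes, 6 rose and 0 fell, including Maff (1.04 ± 0.15) and Fosl1 (0.65 ± 0.10). These 6 are also risers of the immediate early list, so this is not a separate result. Of 6 small leucine-rich proteoglycans, which organise collagen fibrils, 0 rose and 3 fell: Prelp, Bgn and Omd (-1.03 ± 0.11, adjusted p = 0.00388). Bgn was already counted on the matrix list. Of 6 TLE corepressors, 0 rose and 2 fell, Tle2 and Tle6 (at least 1.19-fold lower, adjusted p = 0.0214). Among 20 detected forkhead genes, Foxs1 fell (-0.75 ± 0.14, adjusted p = 0.0343), Foxp1 rose and 18 did not pass. Dusp2 was the 1 riser among 16 dual-specificity phosphatases (0.60 ± 0.10, adjusted p = 0.0218), and 0 of 11 Krueppel-like factors passed with limma, 2 of them at an unadjusted p under 0.05. All 16 called genes of these 7 families had the same sign under each of the 3 scaling alternatives. So had all 240 changed genes, so this does not set the families apart.

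Of 77 distinct kept genes on the p53, stress and immediate early lists, 20 rose and 0 fell. A general heat shock and oxidative stress response stays open: the median of 11 of its genes was -0.000547, but these went both ways and the interval (bootstrap 95% over genes, -0.117 to 0.217) holds the median of the 77 genes, 0.168, with 0 past the threshold with limma and 2 at an unadjusted p under 0.05. An endoplasmic reticulum chaperone response stays open too, because the median of 8 chaperones was 0.0283 with an interval from -0.133 to 0.449, which holds 0.168 as well, with 0 past the threshold and 3 at an unadjusted p under 0.05, and 1, Hspa5 (0.68), past it with the replicate block (adjusted p = 0.0207). Some genes of both sets, such as Srxn1 and Hspa5, are also among the 77, so neither comparison is between separate genes. Both intervals measure the spread between genes and not between arrays. The brighter replicate 3 arrays are argued against as the whole cause. Without both, the median of all 77 genes was 0.161 (bootstrap 95% interval over genes 0.0794 to 0.325) against 0.168 over the 6 arrays. At the preset correlation the p53, stress and immediate early lists kept their calls there. A part of the cause stays open, because the lower end lay just under the bound of 0.5 times that median. The medians in pairs 1 to 3 were 0.05, 0.15 and 0.16 for the stress list, 0.21, 0.26 and 0.15 for the p53 list and 0.27, 0.34 and 0.42 for the immediate early list. A candidate explanation that these data cannot separate from Foxp1 itself is a difference in transfection or culture between the groups, which the labels leave open and which has no test here.

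A broad interferon response, with a rise of at least 0.5 across the list, is argued against by the median of the 23 interferon-stimulated genes, 0.0835 (bootstrap 95% interval over genes -0.0644 to 0.346), of which 6 lay over 0.5 and 10 under 0. One reading is that a few antiviral genes, Oasl1, Isg15 and Ccl5 among them, may rise apart from the rest. Whether foreign DNA or Foxp1 raised them was not tested and stays open.

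The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 240 changed genes (139 higher, 101 lower) and 7 called lists, and was the 1 split of 10 with results that large for each of these counts. The other 9 splits gave at most 0 changed genes with limma and at most 6 called lists. These 9 splits had 97 to 655 genes at an unadjusted p under 0.05, against 1625 in the real split. Each of the 9 has control and Foxp1 arrays on both sides, so a real group difference would add to the spread within sides. Their low gene counts were thus partly set in advance and are no clean measure of chance. The split with 6 called lists set control replicates 1 and 3 and Foxp1 replicate 1 against the rest, so the list count at the preset correlation was nearly as large in a split that does not follow the treatment. The real split is among those that part all 3 numbered pairs; the other 3 of these gave 0, 5 and 5 called lists.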
